A study of Mus musculus with 8 samples.

How the data were processed

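Liver RNA of 8 male C57BL/6 mice was measured, 1 mouse per array, on a 1-colour Mouse OneArray. Per the labels' protocols, the mice were 8 weeks old at the start and ate either a diet lacking methionine and choline (MCD), which brings on fatty liver with inflammation and scarring, or a matched diet sufficient in both (MCS control) for 8 weeks. Animals on the deficient diet were gavaged every day with buffer or with 450 mg/kg diethyldithiocarbamate (DDC), a metal-binding dithiocarbamate and the main metabolite of disulfiram. The groups held 2 MCS control, 3 MCD and 3 MCD+DDC mice. The labels do not state whether control mice were gavaged. Total RNA was extracted with Trizol, amplified and coupled to Cy5, per the labels' protocols.

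The deposited value table held background-subtracted intensity on a linear scale, negative values included. Within each array the values checked, which left out the brightest, were whole multiples of 1 step (100% of them, tolerance 0.02 steps). Each array thus appears to have been multiplied by a single factor. What that factor was set to, the scanner, its software and the background method are not stated in any label or header. The arrays were not on a common level: the 75th percentile was 18.3 and 141 in the controls, 224 to 326 in MCD and 295 to 359 in MCD+DDC. Probes were named through the array layout deposited by the authors, whose annotation date is not given. Of 26423 probes, 22414 had a symbol and 4009 had none. No probe had several. The layout's 19634 symbols were updated through a RefSeq gene table (GRCm38.p6, used for names alone): 17027 were current, 2049 were replaced through a synonym and 558 were kept as printed.

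The test planned before the data were examined was limma on log2 of the deposited values. Because negative values have no logarithm and the arrays differed in level, the values were instead corrected with limma's normexp model (offset 50, no separate background), quantile normalized between arrays and then put on the log2 scale. Quantile normalization had been listed as an alternative to unscaled values, so these exchanged roles. Where a gene had several probes (2439 genes), the probe with the highest mean over the 8 arrays was used, which left 19604 genes. No filter on dim probes was applied. A probe counted as above background on an array when its deposited value exceeded the mode of that array by 3 SD, with the SD taken from values below the mode. Where a gene was above background on no array of a group, its fold change is only a bound. The bright group's mean of normalized log2 values was then set against the dim group's mean of, per array, the higher of the lowest above-background signal and the probe's own, and is written as "at least N-fold". No fold is given where that bound was under 1 or where both groups were below background. For medians of gene lists with such genes at their bound, a gene with no usable bound was set to 0.

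Genes were tested with limma's lmFit and eBayes on all 8 arrays, with 1 coefficient per group (5 residual and 9.43 total degrees of freedom) and Benjamini-Hochberg adjustment over all genes. Genes past an adjusted p of 0.05 are called changed. Errors of fold changes are standard errors of that fit, with n = 2 control, 3 MCD and 3 MCD+DDC arrays. Exact permutation of 3 against 3 arrays cannot give a p below 0.1, and no permutation test of single genes is reported. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated for each list, and with fry. Benjamini-Hochberg adjustment ran over the 31 lists, which held 665 symbols, 607 of them measured. Random lists of the same size, matched on mean level in 20 bins (10000 draws), were added after the data had been examined, as were 26 gene families taken from symbols.

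The genes named were set by a rule fixed before the data were examined. For MCD against control and MCD+DDC against MCD these were the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, with up to 5 places filled by the smallest p where a direction had fewer. Up to 4 members with the smallest unadjusted p came from each described list. In every comparison a panel of 22 genes was added, all of them measured: Col1a1, Col3a1, Acta2, Timp1, Tgfb1, Spp1, Tnf, Ccl2, Adgre1, Cd68, Scd1, Fasn, Cpt1a, Cyp4a14, Cyp2e1, Cyp7a1, Hmox1, Nqo1, Mt1, Mt2, Aldh2 and Alb. Symbols of predicted genes, clone names, olfactory and vomeronasal receptors and immune receptor segments were left out of the largest changes. Where a gene family is described, its members are named as examples chosen after their values were seen.

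The effect of the diet was set against that of the compound across genes. Because both comparisons share the MCD arrays, 100 simulated sets of unchanged groups gave the correlation and covariance that sharing alone brings. A further 100 with the measured diet effect, no compound effect and independent genes were added after the data were examined. Alternatives fixed before the data were examined were a shift of each array to the same median, removal of the dimmest 25% of genes, the mean of all probes of a gene, every probe on its own, eBayes with trend and robust, array weights, a fit on the compared groups alone, the replicate number as a block, each array left out in turn, an unadjusted p with a minimum fold change, a floor at 0 with a pseudocount of 16, an estimated correlation and fry. Values with no scaling, a shift to the same upper quartile, a pseudocount of 1, a filter on genes above background on at least 2 arrays and that filter without MCS control replicate 1 were added after the data had been examined.

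The tests of genes and lists were tried on simulated data of 19604 genes, with 200 genes changed in each of 5 runs. Simulated values started from normalized means, were independent between genes and had the same spread in every group. Background correction, scaling, probe choice and the dimness of the controls were thus not tested, and the error rates hold for such data only. For MCD against control the gene test recovered 0.896% of 1.5-fold, 17.3% of 2-fold and 93.3% of 4-fold changes, with 4.16% of calls wrong. For MCD+DDC against MCD it recovered 1.49%, 37.3% and 97.9%, with 5.23% wrong. All 25 simulated lists shifted by 0.5 were recovered in both comparisons, with 0 wrong calls by camera. The share of genes above background was 15.3% and 39.8% on the control arrays, 51.5%, 52.1% and 60.3% on MCD and 56.5%, 60.1% and 61.4% on MCD+DDC arrays. The number of arrays and the dim control arrays limit the precision. Probes without a symbol were tested apart and left out of the counts of genes. R 4.3.3, limma 3.58.1, python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.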

Results

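Gene expression was measured in liver RNA of 8 male mice, each on its own array. MCS control had 2 mice, MCD had 3 and MCD+DDC, the deficient diet with daily diethyldithiocarbamate, had 3. The arrays differed in brightness. On MCS control replicate 1, 15.3% of the 19604 genes (2990) were above background, and on MCS control replicate 2 it was 39.8% (7796). The MCD and MCD+DDC arrays had 51.5% to 61.4%. Values below zero made up 64.5% and 50.8% of the control arrays and 4.84% to 39.3% of the others. Across genes, the normalized log2 values of both controls correlated at 0.892, those of the MCD arrays at 0.969 to 0.976 and those of the MCD+DDC arrays at 0.949 to 0.979. MCD+DDC replicate 1 gave the lower values of the last range, 0.949 and 0.961. MCD+DDC replicate 2 correlated more with the MCD arrays (0.964, 0.961 and 0.970) than with MCD+DDC replicate 1 (0.949).

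**Figure D1:**
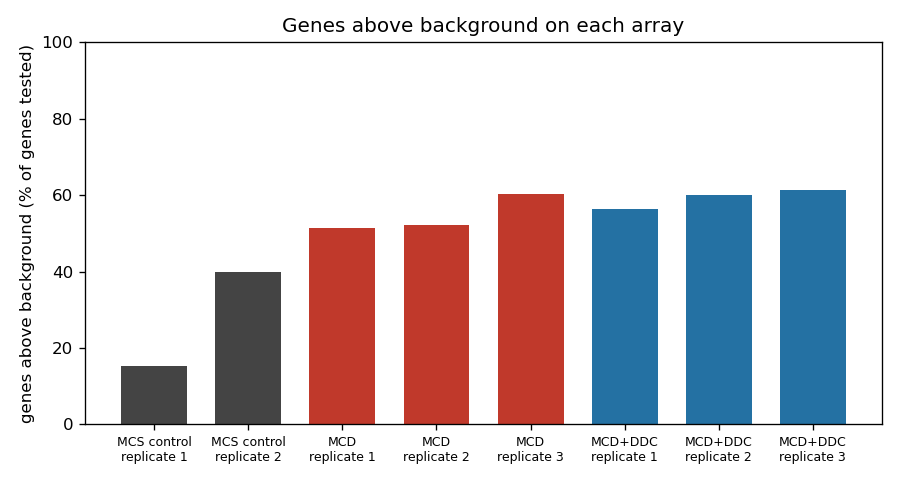
Share of genes above background on each of the 8 arrays, in percent of 19604 genes, coloured by group. The bars start at 0, and the control arrays (15.3% and 39.8%) lie below the other 6 (51.5% to 61.4%).

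The comparison of MCD with MCS control asks what the steatohepatitis diet did to the liver. Gavage may differ along with the diet, as it is not stated for the control mice. Genes of fatty acid oxidation rose as a list (camera adjusted p = 1.56e-05, adjusted p = 0.467 with an estimated correlation). They were led by Cyp4a14, a fatty acid hydroxylase and PPAR alpha target, at least 27.5-fold higher (limma adjusted p = 2.43e-05). The metallothioneins, small metal-binding proteins, rose with them: Mt1 by a log2 fold change of 6.10 (SE 0.47, adjusted p = 0.000386) and Mt2 at least 27.4-fold (adjusted p = 0.000973). Apcs, serum amyloid P of the acute phase, was at least 23.5-fold higher (adjusted p = 0.000408). Marco, a scavenger receptor of Kupffer cells, was at least 8.48-fold higher (adjusted p = 0.000209) and Spp1, osteopontin, at least 3.93-fold higher (adjusted p = 0.00142). Among the largest falls were the urinary protein gene Mup9 (at least 11.7-fold lower, adjusted p = 0.00124) and the lipogenic regulator Thrsp (log2 fold change -4.67, SE 0.56, adjusted p = 0.00145).

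The other large rises included Apoa4, an apolipoprotein of triglyceride-rich particles (5.50, SE 0.32), Gpx3, a secreted glutathione peroxidase (5.37, SE 0.44), and Igfbp1, a fasting-induced binding protein of insulin-like growth factors (5.27, SE 0.24). Apoa4 and Gpx3 were above background on 1 of the control arrays. Serpina7, the thyroxine carrier, was at least 5.83-fold higher (1.29 by another probe, above background on 4 arrays), Asns, asparagine synthetase, at least 5.24-fold and Syndig1, a synaptic membrane protein, at least 7.36-fold. Among the large falls, the small nucleolar RNAs Snord118 (-4.75, SE 0.85), Snora81 (-3.59, SE 0.45) and Snord13 (-3.43, SE 0.76) stood beside Keg1, a glycine acyltransferase-like gene (-3.59, SE 0.35), and Nrep (-3.45, SE 0.38). Car3, carbonic anhydrase of hepatocytes and fat cells, had -3.57 (SE 0.97, adjusted p = 0.0244). Henmt1, a small RNA methyltransferase, was at least 6.63-fold lower and Frmpd3 at least 6.20-fold lower, each above background on 1 control array. Snord13 no longer passed without MCS control replicate 1 (adjusted p = 0.07). Car3 no longer passed without MCS control replicate 2 (0.0895), MCD replicate 1 (0.074) or MCD replicate 2 (0.0818).

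Fatty acid oxidation and PPAR alpha targets rose as a list: 16 of 31 measured members were higher and 1 lower (18 and 2 adjusted over the list alone), with a camera adjusted p of 1.56e-05 and an adjusted p = 0.467 with an estimated correlation. Its median log2 fold change was 1.14, and 0.898 with genes at their bound. Vnn1, pantetheinase (3.64, SE 0.24, above background on 1 control array), and Pex11a, a peroxisome division factor (3.02, SE 0.25), led with Cyp4a14, and Ehhadh, the peroxisomal bifunctional enzyme, was at least 1.11-fold higher. Of the lipid storage list, 11 of 22 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00957, adjusted p = 0.467 with an estimated correlation). The droplet proteins Plin2 (at least 2.82-fold), Plin5 (at least 2.37-fold) and Cidec (at least 2.33-fold) were higher. The median of this list was 0.751 as fitted and 0 with genes at their bound. Oxidative phosphorylation genes rose, 13 of 29 with 0 lower (16 and 1 adjusted over the list alone; camera adjusted p = 0.00582, adjusted p = 0.537 with an estimated correlation). The examples are the complex I subunits Ndufa1 (3.13, SE 0.37, 1 control array) and Ndufv1 (1.64) and the cytochrome oxidase subunit Cox4i1 (1.77). Its median was 0.809, or 0.779 with genes at their bound, but its call was lost when only genes above background on at least 2 arrays were tested (adjusted p = 0.0897). Cytosolic ribosomal protein genes, a family chosen after the data were seen, had a median of 0.184 (camera adjusted p = 0.248). In the 15 of these 42 above background in both groups it was 1.11.

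The acute phase list rose in 8 of 15 members and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000412, adjusted p = 0.467 with an estimated correlation), with a median of 1.09, unchanged with genes at their bound. Of the hepatocyte list, 6 of 18 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.045, adjusted p = 0.631 with an estimated correlation), median 0.777, among them prothrombin F2 (2.51, SE 0.34) and Tat, tyrosine aminotransferase (1.85). Alb, albumin, had -0.14 (adjusted p = 0.733). Metal handling genes rose in 8 of 23 and fell in 0 (9 and 1 adjusted over the list alone; camera adjusted p = 0.045, adjusted p = 0.467 with an estimated correlation). Besides the metallothioneins, Atox1, the copper chaperone, rose by 2.17 (SE 0.29). The median of this list was 0.489, and 0.0855 with genes at their bound. Genes of methionine, choline and 1-carbon metabolism rose in 8 of 25 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.582 with an estimated correlation). Chka, choline kinase (4.03, SE 0.31, 1 control array, and 1.75 by another probe), Mat1a, methionine adenosyltransferase (2.20, SE 0.29), and Chdh, choline dehydrogenase (1.72, 1 control array), were higher, and the list's median was 0.401, or 0.285 at the bounds.

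Extracellular matrix genes rose in 11 of 38 and fell in 4 (11 and 4 adjusted over the list alone; camera adjusted p = 0.045, adjusted p = 0.582 with an estimated correlation). Ccn2, a connective tissue growth factor (at least 3.46-fold), Spp1, Col4a1, a basement membrane collagen (at least 2.03-fold), and Vim, vimentin (3.08, SE 0.34, 1 control array), were higher. The fibrillar collagens Col1a1 and Col3a1 and the protease inhibitor Timp1 were above background on no array of either group. The list's median was 0.413, 0 with genes at their bound, and -0.188 with the arrays shifted to the same upper quartile, which is 0.428 above the median of all genes under that scaling. Macrophage markers rose in 10 of 23 and fell in 1 (11 and 5 adjusted over the list alone; camera adjusted p = 0.0483, adjusted p = 0.467 with an estimated correlation), including Marco, Msr1, another scavenger receptor (at least 1.18-fold), C1qa (2.00, SE 0.38) and Cd68 (adjusted p = 0.00592, no usable bound). Their median was 0.48, and 0 at the bounds. Male-biased liver genes fell in 5 of 11 and rose in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.0147, adjusted p = 0.467 with an estimated correlation), with a median of -1.38, or -1.25 at the bounds. Elovl3, a fatty acid elongase (at least 1.89-fold lower, 1 control array), and the complement gene C8a (-1.49) were examples. The call of this list was lost with arrays shifted to the same median (adjusted p = 0.0986), unscaled (0.0915) or shifted to the same upper quartile (0.0625), while its median stayed negative under all of these. Apart from the extracellular matrix list, the medians of the lists called here kept their sign under the same scalings.

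Leaving out single arrays ended several of these list calls. The matrix list was lost without MCS control replicate 1 (adjusted p = 0.117), MCS control replicate 2 (0.0826) and MCD+DDC replicate 1 (0.052), and the macrophage list without MCS control replicate 2 (0.213), MCD replicate 1 (0.0505) and MCD replicate 2 (0.0542). The hepatocyte list was lost without either control (0.149 and 0.0826) and without MCD replicate 1 (0.0676), and the metal list without either control (0.0722 and 0.142) and without MCD replicate 1 (0.0505). Without MCS control replicate 2 the 1-carbon list (0.0764) and the male-biased list (0.175) were lost too. Testing only genes above background on at least 2 arrays ended the calls of the matrix (adjusted p = 0.181), macrophage (0.152), hepatocyte (0.318), metal (0.159) and 1-carbon lists (0.169). The same 5 lists were lost without the dimmest 25% of genes (0.0651, 0.0864, 0.128, 0.0834 and 0.0571). With pseudocounts of 16 and 1 the matrix (0.056 and 0.0502), hepatocyte (0.0738 and 0.0986) and metal lists (0.112 and 0.119) were lost. Array weights ended the matrix call (0.0611), the mean of all probes the macrophage call (0.0547) and fry the hepatocyte call (0.0525). The fatty acid oxidation, acute phase, lipid storage and oxidative phosphorylation lists passed without any single array.

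The remaining 21 lists did not pass camera in this comparison. Stellate cell markers had 5 higher and 2 lower of 16 (adjusted p = 0.42), inflammatory cytokines 4 and 5 of 26 (0.958), T, NK and B cell markers 1 and 0 of 16 (0.728), neutrophil markers 1 and 0 of 11 (0.794), sinusoidal endothelial markers 4 and 1 of 14 (0.794) and cholangiocyte markers 3 and 0 of 14 (0.794). Erythrocyte markers had 0 called of 4 (0.728) and markers of adipose tissue, pancreas and muscle 2 lower of 13 (0.0586). De novo lipogenesis had 7 higher and 2 lower of 20 (0.201). Fads2, a fatty acid desaturase, was at 3.51 (1 control array) and Scd1, stearoyl-CoA desaturase, at -3.34 (SE 0.75, adjusted p = 0.0122). Cholesterol synthesis had 3 and 0 of 23 (0.651), bile acid genes 5 and 5 of 22 (0.958), xenobiotic cytochromes 3 and 4 of 16 (0.947) and NRF2 targets 7 and 1 of 28 (0.0617). Dehydrogenases of alcohols and aldehydes had 4 and 2 of 21 (0.728), the integrated stress response 7 and 2 of 21 (0.155), with Trib3, a stress-induced pseudokinase, at least 6.46-fold higher. Cell cycle genes had 3 and 4 of 24 (0.982), p53 targets 5 and 1 of 20 (0.559), interferon-stimulated genes 4 and 2 of 20 (0.958), female-biased genes 4 and 1 of 11 (0.794), glucose genes 6 and 1 of 17 (0.257) and clock genes 2 and 2 of 18 (0.982). Adjusted over the list alone, the counts of these lists were the same or moved by at most 3 genes. The median and the mean differed in sign for the endothelial (-0.0475 and 0.175), cholangiocyte (-0.358 and 0.0847), bile acid (-0.0809 and 0.108), glucose (-0.029 and 0.556) and clock lists (0.148 and -0.0238). Camera's direction differed from the mean for the inflammatory (0.0831), cholangiocyte and bile acid lists (down) and for the clock list (up).

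Of the gene panel, Cyp2e1, an ethanol-inducible cytochrome, rose by 1.64 (SE 0.31), and Hmox1, heme oxygenase, was at least 1.83-fold higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.80 (SE 0.40, adjusted p = 0.0114), but not past the threshold without MCS control replicate 1 (0.058). Cpt1a, the gatekeeper of mitochondrial fatty acid import, was at 1.91 (SE 0.34, 1 control array), while another of its probes had -1.21. Tgfb1, a profibrotic cytokine, was lower by the fit (-0.98, adjusted p = 0.021, above background on 1 control array) and was not past the threshold without MCS control replicate 1 (0.0725), MCD replicate 2 (0.0652) or MCD replicate 3 (0.0681). Tnf had -1.46 (adjusted p = 0.0358, above background on 2 MCD arrays and 1 control array) and was lost without either control (0.0565 and 0.117), MCD replicate 1 (0.0967), MCD replicate 2 (0.0968), MCD+DDC replicate 1 (0.0516) or MCD+DDC replicate 3 (0.0561). Adgre1, the F4/80 macrophage antigen, passed (adjusted p = 0.0215) with no usable bound. It was lost without MCS control replicate 2 (0.0539) and MCD replicates 1 to 3 (0.0514, 0.0607 and 0.0687), and its sign turned under upper quartile scaling. Aldh2, the mitochondrial aldehyde dehydrogenase, had -0.63 (adjusted p = 0.0359), with a positive sign when arrays were shifted to the same median or left unscaled. It was lost without MCS control replicate 1 (0.0988), MCS control replicate 2 (0.0564), MCD replicates 1 to 3 (0.0992, 0.0781 and 0.0618) and MCD+DDC replicate 3 (0.0662). Acta2, the smooth muscle actin of activated stellate cells, had 0.62 (adjusted p = 0.107), and Ccl2, Nqo1 and Fasn were below background in both groups.

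In all, limma called 5534 genes between MCD and MCS control, 3271 higher and 2263 lower. The fit takes 1 spread for all groups, while limma's array weights were 0.33 for each control and 0.505 to 6.55 for the other arrays. Standard errors of this comparison may thus be too small, and with array weights 2282 genes were called. At an unadjusted p under 0.05 there were 8176, and the groups did not overlap for 54.4% of all genes, where chance gives 20%. Of the higher genes, 1655 were above background on no control array, 64 of them on no MCD array either. Among the 595 olfactory and vomeronasal receptor genes, which the liver does not use, 17.0% were called (99 lower and 2 higher) against 28.2% of all genes. Called lower were 16.6% of them, against 11.5% of all genes. Of these 595, 199 were above background on at least 1 array. The count was 3501 without MCS control replicate 1, 7919 without MCS control replicate 2, 3680, 2846 and 3367 without MCD replicates 1 to 3, and 4363 to 5776 without an MCD+DDC array. The split between higher and lower depended on the scaling: 59.1% of calls were higher as normalized, 94.5% with arrays shifted to the same median, 91.5% unscaled and 24.2% with arrays shifted to the same upper quartile. The median of all genes was -0.615 under the upper quartile, 0.113 with the shift to the same median and -0.0239 as normalized.

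**Figure D2:**
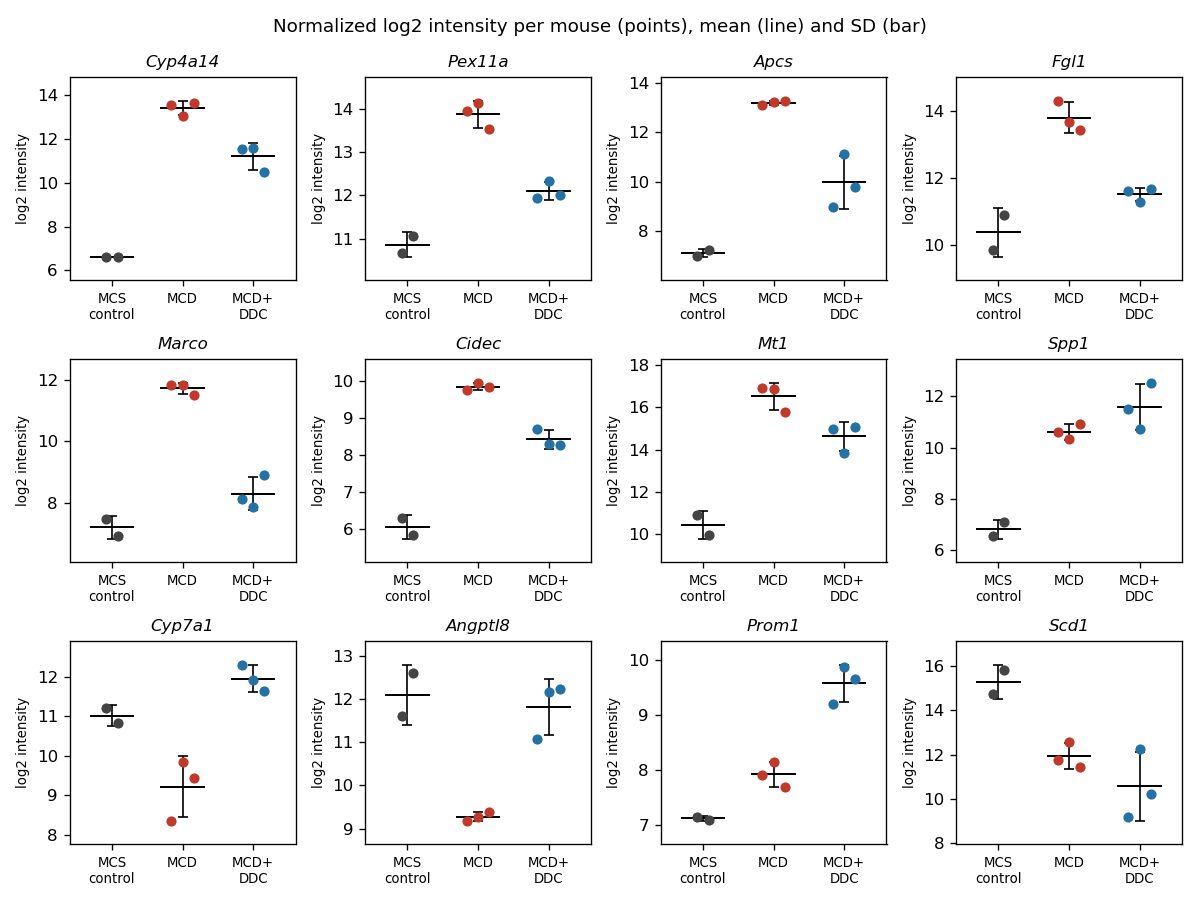
Normalized log2 intensity of 12 genes in each mouse (points), with the group mean (line) and SD (bar) for MCS control (n = 2), MCD (n = 3) and MCD+DDC (n = 3). Cyp4a14, Pex11a, Apcs, Fgl1, Marco and Cidec were highest in MCD and lower in MCD+DDC, while Cyp7a1, Angptl8 and Prom1 were higher in MCD+DDC than in MCD.

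The comparison of MCD+DDC with MCD asks what the compound did in mice on the deficient diet. Acute phase and fatty acid oxidation genes were lower with DDC as lists (camera adjusted p = 1.57e-15 and 4.19e-15, adjusted p = 0.103 and 0.112 with an estimated correlation). Cytosolic ribosomal protein genes, short messages of every cell, were lower beside them (camera adjusted p = 0.000149, adjusted p = 0.133 with an estimated correlation, median -0.175, and -0.566 in the 25 of 42 above background in both groups; negative under the other scalings). Apcs fell by 3.22 on the log2 scale (SE 0.44, adjusted p = 0.0361), Fgl1, a fibrinogen-like hepatokine, by 2.30 (SE 0.31, adjusted p = 0.0361) and Cyp4a14 by 2.21 (SE 0.31, adjusted p = 0.0361). Marco fell by 3.43 (SE 0.28, adjusted p = 0.00415) and Serpina7 by 2.94 (SE 0.21, adjusted p = 0.00245), while another probe of Serpina7, above background on 4 arrays, had -0.71. Cyp7a1 rose by 2.74 (SE 0.36, adjusted p = 0.0336), as did Angptl8, an insulin-induced inhibitor of lipoprotein lipase, by 2.54 (SE 0.34, adjusted p = 0.0361). In each of these genes the 3 MCD+DDC mice did not overlap the 3 MCD mice, as the rule for naming them required.

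The other rises were Clec7a, the beta-glucan receptor dectin-1 of macrophages (1.78, SE 0.19), Robo1, a receptor for Slit guidance proteins (1.73), Prom1, a marker of progenitor and bile duct cells (1.67), Arl4d, a small GTPase (1.31), and Sh3bp2, an adaptor of immune signalling (1.27). Another probe of Prom1, above background on 6 arrays, had -0.19. Falls included Avpi1, a vasopressin-induced gene (-2.73, SE 0.31), and the mitochondrial genes Ndufa1 (-2.29, SE 0.33), Micos13, of the cristae junction complex (-2.19, SE 0.25), and Ndufb2 (-1.90). The acute phase genes Itih4 (-2.03) and Hpx, hemopexin (-1.66), also fell. So did Pex11a (-1.78), Cidec (-1.43) and Apoc3, an inhibitor of triglyceride clearance (-1.71), while Ehhadh was at least 3.41-fold lower, with no MCD+DDC array above background. Their limma adjusted p ranged from 0.0204 to 0.0413. The remaining 3 called genes, Ctla2a, Tmem120a and Ntsr2, were also lower and are named here outside the rule.

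All 15 measured acute phase genes had negative fold changes, with a median of -1.19, and medians of -1.40, -1.18 and -0.83 in MCD+DDC replicates 1 to 3 against the MCD mean. Of these genes, 4 were called lower (10 adjusted over the list alone; camera adjusted p = 1.57e-15, adjusted p = 0.103 with an estimated correlation). Of the fatty acid oxidation list, 3 of 31 were called lower (14 adjusted over the list alone; camera adjusted p = 4.19e-15, adjusted p = 0.112 with an estimated correlation), and the median was -0.77, with -0.95, -0.43 and -0.89 in the 3 mice. Oxidative phosphorylation genes fell as a list, 25 of 29 negative and 1 called (7 adjusted over the list alone; camera adjusted p = 4.39e-08, adjusted p = 0.186 with an estimated correlation), median -0.465. The lipid storage list fell, with 1 of 22 called (5 adjusted over the list alone; camera adjusted p = 0.000111, adjusted p = 0.112 with an estimated correlation). Plin5 had -1.67 (adjusted p = 0.0542) and Plin2 -1.30 (adjusted p = 0.0967) in that list, whose median was -0.263, or -0.224 at the bounds. Sinusoidal endothelial markers fell with 0 of 14 called (3 lower adjusted over the list alone; camera adjusted p = 3.05e-05, adjusted p = 0.103 with an estimated correlation), median -0.453, or -0.443 at the bounds. Egfl7, secreted by endothelial cells, had -1.83 (adjusted p = 0.063), and Lyve1, the sinusoidal hyaluronan receptor, was at least 1.39-fold lower (adjusted p = 0.0647). These 5 lists passed without any single array, and fry called each but oxidative phosphorylation (fry adjusted p = 0.0773).

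A further 7 lists passed camera, depended on single arrays and were not called by fry (fry adjusted p = 0.136 to 0.36). The hepatocyte list was lower (1 of 18 called, 6 adjusted over the list alone; camera adjusted p = 0.00312, adjusted p = 0.425 with an estimated correlation), median -0.277, with prothrombin F2 at -1.28 (adjusted p = 0.124) and Alb at 0.42 (adjusted p = 0.665). Without MCD+DDC replicate 1 it was lost (0.105). De novo lipogenesis was lower with 0 of 20 called (0 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.425 with an estimated correlation), median -0.325, and was lost without MCD replicate 2 (0.0521), without MCD+DDC replicate 1 (0.212), with arrays shifted to the same median (0.138) and with a pseudocount of 1 (0.0923). Dgat2, an enzyme of triglyceride synthesis, had -1.24 (adjusted p = 0.155) and Scd1 -1.37 (SE 0.67, adjusted p = 0.555). Erythrocyte markers were lower, 0 of 4 called (1 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.425 with an estimated correlation), median -0.491, or -0.305 at the bounds, and were lost without MCD replicate 2 (0.0785) or MCD+DDC replicate 1 (0.08), and with genes above background on at least 2 arrays (0.0979). The metal list was lower, 0 of 23 called (2 lower adjusted over the list alone; camera adjusted p = 0.036, adjusted p = 0.363 with an estimated correlation), median -0.154, with Mt1 at -1.89 (adjusted p = 0.102) and Mt2 at -0.85 (adjusted p = 0.805). It was lost without MCD replicate 1 (0.0941), MCD replicate 2 (0.0538) or MCD+DDC replicate 1 (0.236), with array weights (0.144) and with pseudocounts of 16 (0.109) and 1 (0.312).

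The other 3 of these lists were higher with DDC. Cholangiocyte and progenitor markers had 1 of 14 called (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.363 with an estimated correlation), median 0.393, or 0.158 at the bounds. Prom1 led this list, Sox4, a progenitor transcription factor, had 1.02 (adjusted p = 0.0967), and the call was lost without MCD+DDC replicate 1 (0.08) or without the dimmest 25% of genes (0.054). Inflammatory cytokines and chemokines had 0 of 26 called (0 adjusted over the list alone; camera adjusted p = 0.00524, adjusted p = 0.268 with an estimated correlation), median 0.234, or 0.0698 at the bounds. Icam1, an adhesion molecule, had 1.16 (adjusted p = 0.227) and Tnf 0.69 (adjusted p = 0.664), and the call was lost without MCD replicate 2 (0.0594). Interferon-stimulated genes had 0 of 20 called (0 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.363 with an estimated correlation), median 0.229, or 0.0573 at the bounds, with Irf7, an interferon regulator, at 1.06 (adjusted p = 0.253). That call was lost without MCD replicate 2 (0.0996) or MCD+DDC replicate 3 (0.0886), and with genes above background on at least 2 arrays (0.146). The medians of the 12 lists called with DDC kept their sign when arrays were left unscaled or shifted to the same median or upper quartile.

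No collagen or stellate cell gene of the panel passed the test for DDC. The matrix list had 0 of 38 called by limma (camera adjusted p = 0.0902, 24 positive and 14 negative, median 0.0969), and stellate cell markers 0 of 16 (0.437). Spp1 had 0.98 (adjusted p = 0.424), Acta2 0.67 (adjusted p = 0.322) and Tgfb1 -0.31 (adjusted p = 0.809). Col1a1, Col3a1, Ccl2, Fasn and Nqo1 were below background in both groups, and Timp1 was above it on 2 MCD+DDC arrays and on no MCD array. Macrophage markers had Marco lower of 23 (0.884), and their median (0.0534) and mean (-0.147) differed in sign. Cd5l, a lipid-binding protein of macrophages, had -2.05 (adjusted p = 0.0593), Gpnmb, of lipid-laden macrophages, 1.66 (adjusted p = 0.082), Adgre1 -0.38 (adjusted p = 0.539) and Cd68 0.40 (adjusted p = 0.432).

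Camera did not pass the other 16 lists. T, NK and B cell markers (adjusted p = 0.134), neutrophil markers (0.283), adipose, pancreas and muscle markers (0.939), cholesterol synthesis (0.368), xenobiotic cytochromes (0.0902) and NRF2 targets (0.359) had 0 genes called. The same held for dehydrogenases of alcohols and aldehydes (0.926), the 1-carbon list (0.103), the integrated stress response (0.926), the cell cycle (0.479), p53 targets (0.266), male-biased genes (0.707), glucose genes (0.972) and clock genes (0.939). Bile acid genes had Cyp7a1 higher of 22 (0.479), and female-biased genes had Prom1 higher of 11 (0.319). Adjusted over the list alone, NRF2 targets had 4 higher and 3 lower and the macrophage list 2 higher and 4 lower, with Osgin1, an oxidative stress growth inhibitor, at 2.11 (adjusted p = 0.0547) and Gstm3, a glutathione transferase, at 2.26 (adjusted p = 0.0547). In the bile acid list there were 2 higher and 2 lower, in the female-biased list 2 and 1, and the stellate, 1-carbon and stress response lists had 1 each way. Male-biased genes had 1 higher, and the others named in this and the preceding paragraph had 0. The median and the mean differed in sign for the dehydrogenases (0.0732 and -0.0213), adipose, pancreas and muscle (-0.0106 and 0.0178), stress response (-0.000339 and 0.0299), male-biased (-0.0167 and 0.113), glucose (-0.0568 and 0.0332) and clock lists (-0.0522 and 0.101). Camera's direction went with the mean for the last 4 of these and with the median for the dehydrogenase and the adipose, pancreas and muscle lists. Of the panel, Cpt1a had -0.58 (adjusted p = 0.608), Cyp2e1 -0.41 (0.766), Hmox1 -0.63 (0.743) and Aldh2 0.14 (0.961).

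Altogether limma called 25 genes between MCD+DDC and MCD, 7 higher and 18 lower. The errors use a spread shared with the controls, whose arrays correlated at 0.892, which need not hold for MCD and MCD+DDC. At an unadjusted p under 0.05 there were 2005, and the groups did not overlap for 19.1% of all genes, where chance gives 10%. The count was 4, 1 and 4 without MCD replicates 1 to 3, 1 and 2 without MCD+DDC replicates 1 and 3, and 277 without MCD+DDC replicate 2. It was 152 and 203 without MCS control replicates 1 and 2, and 191 when only MCD and MCD+DDC arrays were fitted, the same 25 among them. The scaling mattered too: 2 genes, both lower, passed with arrays shifted to the same median, 3 (1 higher) unscaled and 374 (131 higher) with arrays shifted to the same upper quartile. The median of all genes was 0.13 unscaled, -0.132 under the upper quartile and 0.000834 as normalized. Array weights gave 2090 calls, 1124 higher and 966 lower, the 25 among them, and a floor at 0 gave 4 (2 higher) with a pseudocount of 16 and 1, higher and not among the 25, with a pseudocount of 1. Serpina7 passed without any single array and was lost with a pseudocount of 1 (adjusted p = 0.0898). Marco was lost without MCD replicate 2 (adjusted p = 0.0634) and MCD+DDC replicate 1 (0.0505), and of the 22 named calls 19 to 21 were lost without each of MCD replicates 1 to 3 and MCD+DDC replicates 1 and 3, at an adjusted p of 0.0505 to 0.276.

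**Figure D3:**
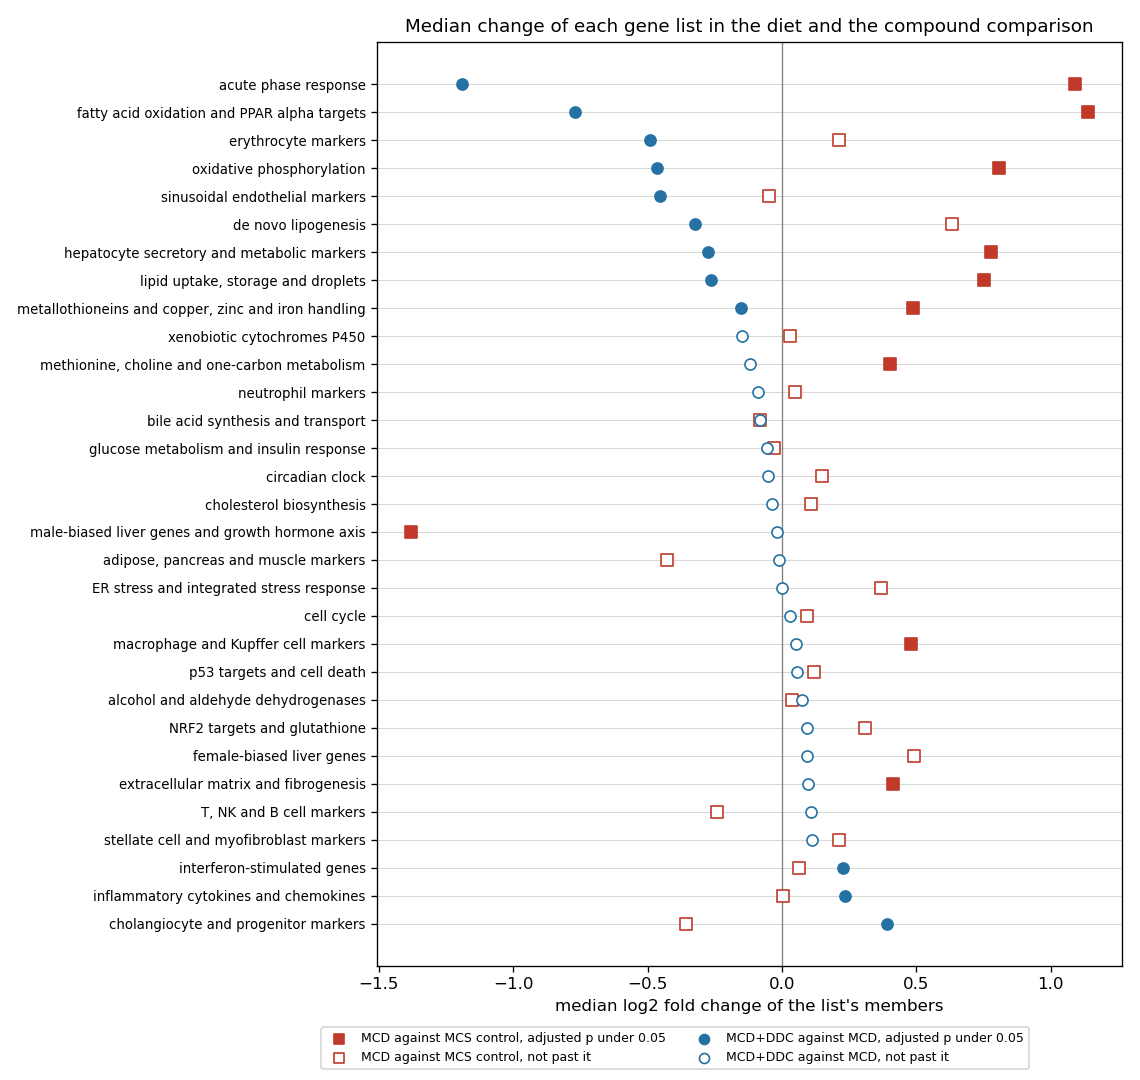
Median log2 fold change of the 31 gene lists for MCD against MCS control (squares) and MCD+DDC against MCD (circles), filled where the camera adjusted p was under 0.05. The acute phase and fatty acid oxidation lists lie at 1.09 and 1.14 for the diet and at -1.19 and -0.77 for the compound, and these kept their sign under the other scalings. Both comparisons share the MCD arrays, which favours opposite signs.

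The comparison of MCD+DDC with MCS control asks what separated treated mice from mice on the sufficient diet. Panel genes that rose on the diet were in part also higher here. Mt1 was higher by 4.21 (SE 0.47, adjusted p = 0.00121), Mt2 at least 15.2-fold (adjusted p = 0.00152) and Cyp4a14 at least 5.94-fold (adjusted p = 0.000437). Spp1 was at least 7.77-fold higher (adjusted p = 0.000695), and Acta2 was higher by 1.29 (adjusted p = 0.00952, 1 control array). Scd1 was lower by a log2 fold change of -4.71 (SE 0.75, adjusted p = 0.00386) and Tgfb1 by -1.29 (adjusted p = 0.00818).

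Cd68 passed with no usable bound (adjusted p = 0.00202), Cyp2e1 was at 1.24 (adjusted p = 0.0184), Hmox1 at least 1.19-fold higher (adjusted p = 0.012) and Cpt1a at 1.33 (adjusted p = 0.0213, 1 control array, sign turned with the mean of its probes). Without MCS control replicate 1, Cpt1a (0.0658) and Hmox1 (0.0537) were lost, and Cyp2e1 was lost without MCS control replicate 2 (0.0605) or MCD+DDC replicate 2 (0.0557). Cyp7a1 had 0.94 (adjusted p = 0.107), Tnf -0.77 (0.219), Aldh2 -0.48 (0.0858) and Alb 0.28 (0.455), and Adgre1 did not pass (0.171). In total, 5252 genes were called by limma, 3083 higher and 2169 lower, with 8036 at an unadjusted p under 0.05. Higher genes made up 58.7% of the calls as normalized, 78.8% with arrays shifted to the same median, 92.2% unscaled and 19.6% with arrays shifted to the same upper quartile. The median of all genes was -0.0207, 0.113, 0.233 and -0.683 in that order. The count was 3284 and 7697 without MCS control replicates 1 and 2, and 2875 and 2218 without MCD+DDC replicates 2 and 3. Camera called 0 of the 31 lists (9 at an unadjusted p under 0.05, lowest adjusted p = 0.0525 for the matrix list), and fry called 13.

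Setting the effect of the diet against that of the compound asks whether DDC moved genes back toward the control level. Of the 25 genes called with DDC, 24 were also called for the diet and 22 moved the opposite way. Higher on the diet and lower with DDC were 18 genes, among them Cyp4a14, Apcs, Marco, Cidec and Serpina7, and 4 were lower on the diet and higher with DDC, Cyp7a1 among them. A further 2 were higher in both and 0 lower in both. Independent lists would give 3.00, 0.808, 1.17 and 2.08, but both comparisons share the MCD arrays, which favours opposite signs. In 100 simulations with the measured diet effect, no compound effect and shared MCD arrays, added after the data were examined, the 25 genes with the smallest p for the compound held 11.7 opposite diet calls on average (5 to 18). Those higher on the diet and lower with the compound numbered 5.88 (2 to 13). Of these 25 simulated genes, 16 on average (10 to 23) were called for the diet, against 24 measured. The simulated genes varied independently of each other, which real genes do not. Still called against MCS control were 12 of the 25.

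Across all genes the fold changes of diet and compound correlated at -0.295 (Spearman -0.198), with a covariance of -0.0919, and 62.7% of the diet genes had the opposite sign with DDC. Genes are not independent replicates, and sharing the MCD arrays alone brings such values. The same simulations, with the measured diet effect and no compound effect, gave a correlation of -0.147 (-0.173 to -0.125), a covariance of -0.0336 (-0.0397 to -0.0284) and 58.0% opposite (56.2% to 59.4%). The 3 measured values lay outside these ranges, which are too narrow where genes vary together. These simulations added noise to measured means that already hold noise, and called 7500 genes for the diet (7358 to 7686) against 5534 measured. Their correlation and opposite share are therefore not an exact baseline. With no effect of either, the simulated correlation was -0.446 (-0.459 to -0.427), the covariance -0.0334, which leaves a difference of -0.0586, and 64.8% of all genes were opposite. These do not carry the spread of the diet effect, so the correlation and share are not set against them. With genes called on 2 MCD arrays and the compound effect taken against the MCD array left out, which shares no array, the opposite share was 51.2%, 66.8% and 59.8% for MCD replicates 1 to 3. Among genes higher on the diet it was 56.1%, 68.5% and 61.1%, and among genes lower on the diet 42.0%, 63.3% and 57.1%. The correlation was then -0.0896, -0.267 and -0.194, the covariance -0.0322, -0.103 and -0.0677, and 49.7%, 48.6% and 51.2% of all genes had a positive compound fold change. The correlation was -0.141 without MCD+DDC replicate 1, -0.181 without quantile normalization, -0.193 with array weights and -0.177 with a pseudocount of 1. No simulation was run for these settings. The other scalings differ from each other by a constant per array, so all of them give the same correlation by construction.

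**Figure D4:**
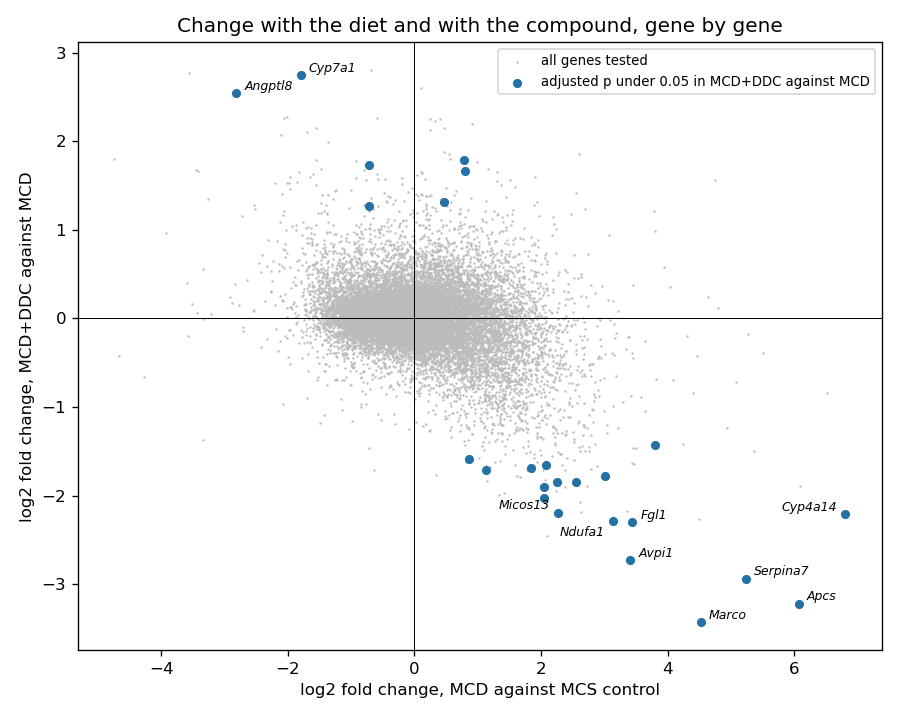
Log2 fold change of each gene with DDC (MCD+DDC against MCD) against its log2 fold change on the diet (MCD against MCS control), with the 25 genes called for DDC in blue. The 18 genes in the lower right were higher on the diet and lower with DDC, and both axes share the MCD arrays, which alone tilt the cloud downward.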

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

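Of the tests in this part, those on the share of hepatocytes and on control RNA handled apart, and the margin and the above-background subset of the ribosomal protein test, were chosen after the result was seen. A signal lay in probes that no comparison of genes used: limma, fitted to the 4009 probes without a gene symbol, called 4 of them between MCD+DDC and MCD, 3 higher and 1 lower. Probe PH_mM_0008460 was higher by 1.50 (SE 0.16, adjusted p = 0.0102) and probe PH_mM_0012964 lower, at -1.52 (SE 0.17, adjusted p = 0.0102). The files do not pair these probes with a gene. Groups of 2 or 3 arrays were not tested for a single array far from its group, but limma's array weights were 0.33 for each control, 1.07 to 1.66 for MCD and 0.505, 1.15 and 6.55 for MCD+DDC replicates 1 to 3.

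Acute phase and fatty acid oxidation genes were lower in MCD+DDC than in MCD, for which an action of DDC stays open, untested. A lower share of hepatocytes stays open. It would raise markers of the other cell types alike, but cholangiocyte markers were higher (0.393) and endothelial markers lower (-0.453). The 10 brightest hepatocyte markers outside both lists had a median of -0.136, against -1.19 for the acute phase and -0.769 for the fatty acid list. These markers went both ways, from Alb (0.42) and Tat (0.82) to Apoa2 (-0.83), Fgb (-1.34) and Apoc3 (-1.71), so their median does not decide. The hepatocyte list as such was lower (camera adjusted p = 0.00312, adjusted p = 0.425 with an estimated correlation), as were the medians of apolipoproteins (-0.398) and coagulation factors (-0.383). Loss of short messages through RNA quality remains open, since the 42 cytosolic ribosomal protein genes had a median of -0.175, above the bound of -0.2 set beforehand against it by less than their spread, while the 25 above background in both groups had -0.566, past the -0.4 set beforehand for it. The 10 splits of these 6 arrays are too few for a share under 0.05: 1 split, the real one, gave at least its 25 genes (highest other 0), and 3 gave at least its 12 lists, the others exchanging MCD+DDC replicate 2 with MCD replicate 3 (18, the highest other) or MCD replicate 2 (17).

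Of all genes, 28.2% were called between MCD and MCS control. The test of MCS control replicate 1 alone as the cause covered the 2938 genes above background on all 8 arrays. Of these, 26.2% were called without that array, where under 5% would have pointed to it, and 45.9% with both controls. This argues against that array alone for these genes only. They held 436 of the 3271 genes called higher and 913 of the 2263 called lower, and for the other calls the question stays open. Noise of the dim control arrays remains open, because 17% of 595 receptor genes that the liver does not use were called. That is more than the 5% that would have excluded it and fewer than the 28.2% of all genes. Nearly all these calls were lower, however, and 16.6% of the receptors were called lower against 11.5% of all genes. Of these receptors, 133 were above background in both groups, so they need not measure noise alone and the test cannot decide. An effect of the diet, which the design names, or of gavage if controls had none, was not tested apart from these, since each control array lies in 1 group.

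Small nucleolar RNA genes were lower in MCD than in MCS control, 17 of 63 (27.0%, against 11.5% of all genes), with a median of -0.316 that stayed negative under each scaling tried but was 0 with genes at their bound (camera adjusted p = 0.0034, adjusted p = 0.423 with an estimated correlation). Noise in dim probes may account for part of this, as 35.3% of those 17 (6 genes) were above background on both control arrays, under the share of over 50% that would have argued against it, and the 595 receptor genes that the liver does not use had nearly the same median (-0.307, 16.6% called lower, camera adjusted p = 1.98e-06, adjusted p = 0.258 with an estimated correlation). Among members above background in both groups the medians were lower still, -0.712 in 22 small nucleolar RNA genes and -0.891 in 133 receptors. These members were picked by the same control values that form the fold change, so noise could lower their medians too. They cannot decide whether dimness is the cause. Control RNA prepared or labelled apart from the rest cannot be told apart from the diet, because both controls are 1 group. In MCD+DDC against MCD those 17 genes had a median of -0.0367, while it was -1.12 in MCD against control. Daily gavage cannot be told apart from the diet either, since the labels do not state whether control mice were gavaged. Neither was tested.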

How the results depend on the processing

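The scaling without adjustment, the shift to the same upper quartile, the pseudocount of 1, the filter on genes above background and that filter without MCS control replicate 1 were chosen after the data were seen. Main counts of called genes were 5534 (diet), 25 (DDC against MCD) and 5252 (DDC against control), with 10 and 12 lists and a diet to compound correlation of -0.295. With arrays shifted to the same median there were 2 genes for DDC against MCD and unscaled 3. Shifted to the same upper quartile there were 374, with 9985 for the diet and 11135 for DDC against control. The correlation was -0.181 in all of these by construction, as they differ by a constant per array. Array weights gave 2282, 2090 and 3473 genes in that order and -0.193. Fitting the compared groups alone gave 191 genes for DDC against MCD and 2374 against control. A floor with pseudocount 16 gave 4 genes for DDC against MCD, and pseudocount 1 gave 1, with 3163 for the diet and -0.177. Genes above background on at least 2 arrays gave 54 for DDC against MCD and 5 diet lists. That filter without MCS control replicate 1 gave 3350, 258 and 2963 genes and 5 diet lists. An unadjusted p with a minimum fold change gave 494 for DDC against MCD. Without the dimmest 25% of genes 6 diet lists passed. With an estimated correlation 0 lists passed in both comparisons by camera, and fry called 15 for the diet and 4 for DDC. Tests on fewer genes or arrays differ by construction; for the other settings the cause was not tested.

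Leaving out 1 array gave 2846 to 7919 genes for the diet, 1 to 277 for DDC against MCD and 2218 to 7697 for DDC against control, 4 to 10 diet lists, 7 to 15 DDC lists and correlations of -0.367 to -0.141. A lone control is assumed to vary like the other groups. Over 128 named diet calls, 2544 of 2807 pairs of gene and setting kept the call, 253 were weaker and 10 reversed, and 73 genes kept it throughout. Over 22 named DDC calls, 288 of 484 pairs kept the call and 196 were weaker, with 0 reversed, and no gene kept it throughout. Against control, 228 of 242 pairs kept the 11 calls, 13 were weaker and 1 reversed. For the diet, the sign of Cel (0.224), Nr1h4 (0.225) and Aldh2 (0.569) turned with arrays shifted to the same median, and that of the same genes unscaled (0.149, 0.15 and 0.494). Under the upper quartile Cd3d (-0.105), Gbp3 (-0.19), Ifit2 (-0.106) and Adgre1 (-0.051) turned by the shift of whole arrays, each still above the median of all genes there (-0.615). The reversed call against control was Cpt1a with the mean of its probes (-0.051). Fasn, not called and below background in both groups, passed against control only under the upper quartile (-1.04), where the median of all genes was -0.683. The cause was not tested for the other turns.

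Whether replicate numbers pair the mice stays open, as the labels do not say so. Same-numbered MCD and MCD+DDC arrays deviated together with correlations of 0.189, 0.0992 and 0.219, not all above 0.1. Differently numbered ones had -0.206 to 0.0766, so each MCD array correlated best with its own number, a hint of pairing from the data. With the replicate block there were 4656, 20 (13 shared with the 25) and 4308 genes, the diet's matrix list (adjusted p = 0.0514) and macrophage list (0.0753) did not pass, and the block ended no other list call. Signal over background also limits the diet comparison: 11795 genes were above background on no control array, against 7592 in MCD and 6944 in MCD+DDC, so many diet changes are bounds.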

Other observations

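The gene families in this part, their members named and the random lists were chosen after the data were seen. Of the families of mitochondrial proteins and protein turnover, 4 were higher as lists on the diet and lower with DDC, and cytochrome oxidase subunits were not (4 higher of 16 on the diet, median -0.0176, camera adjusted p = 0.733; 0 called with DDC, median -0.0316, camera adjusted p = 0.228). Cytosolic ribosomal protein genes were lower with DDC beside them (camera adjusted p = 0.000149, adjusted p = 0.133 with an estimated correlation, median -0.175, and -0.566 in the 25 above background in both groups). On the diet 10 of these 42 were higher and 2 lower (camera adjusted p = 0.248), with a median of 0.184, and 1.11 in the 15 above background in both groups. Mitochondrial ribosomal proteins, which make the proteins encoded by mitochondrial DNA, had 35 higher and 2 lower of 69 on the diet (camera adjusted p = 6.25e-07, adjusted p = 0.343 with an estimated correlation, median 0.924, or 0.882 with genes at their bound) and 59 of 69 negative with DDC (0 called by limma, camera adjusted p = 9.27e-15, adjusted p = 0.157 with an estimated correlation, median -0.433). Mrpl46, of the large subunit, had -1.64 with DDC (adjusted p = 0.0547). Complex I subunits had 18 higher and 2 lower of 35 on the diet (camera adjusted p = 0.000191, adjusted p = 0.39 with an estimated correlation, median 0.781, or 0.661 at the bounds). With DDC 30 of 35 were negative and Ndufa1 and Ndufb2 were called (camera adjusted p = 1.98e-15, adjusted p = 0.157 with an estimated correlation, median -0.646). ATP synthase subunits had 6 higher of 12 on the diet (camera adjusted p = 0.0348, adjusted p = 0.343 with an estimated correlation) and 9 of 12 negative with DDC (camera adjusted p = 2.41e-07, adjusted p = 0.133 with an estimated correlation, median -0.984). Proteasome subunits, which degrade tagged proteins, had 23 higher and 1 lower of 38 on the diet (camera adjusted p = 3.9e-06, adjusted p = 0.258 with an estimated correlation), with Psmd4 at 2.04 (adjusted p = 0.00171), and 29 of 38 negative with DDC (camera adjusted p = 1.36e-07, adjusted p = 0.133 with an estimated correlation). The medians of these 4 families kept their sign in both comparisons when arrays were unscaled or shifted to the same median or upper quartile. Both comparisons share the MCD arrays, which favours opposite signs, and no simulation of this was run for any family or list. By mouse, the MCD+DDC medians against the MCD mean were -0.62, -0.26 and -0.51 for mitochondrial ribosomal proteins and -0.90, -0.35 and -0.68 for complex I.

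Apolipoproteins, the carriers of blood lipids, had 9 higher and 0 lower of 13 on the diet (camera adjusted p = 0.000154, adjusted p = 0.258 with an estimated correlation, median 1.13) and a median of -0.398 with DDC, with Apoc3 called (camera adjusted p = 7.84e-07, adjusted p = 0.133 with an estimated correlation). These signs held under the same scalings. Coagulation factors had 12 of 17 negative with DDC (0 called, camera adjusted p = 0.00037, adjusted p = 0.17 with an estimated correlation, median -0.383, negative under the same scalings). Keratins, the filament proteins of epithelia, had 10 lower of 52 on the diet (camera adjusted p = 0.0034, adjusted p = 0.258 with an estimated correlation, median -0.392, 0 with genes at their bound, negative under the same scalings). The 595 olfactory and vomeronasal receptor genes, which the liver does not use, fell alike (16.6% called lower against 19.2% of keratins, median -0.307, camera adjusted p = 1.98e-06, adjusted p = 0.258 with an estimated correlation). The keratin fall is thus not told apart from that of the receptor genes. Among members above background in both groups the medians were lower still, -0.662 in 23 keratins and -0.891 in 133 receptors. These were picked by the same control values that form the fold change, so their medians cannot decide on noise. Whether dim probes account for the fall stays open. Annexins and S100 proteins had 7 higher and 3 lower of 26 on the diet (camera adjusted p = 0.0471, adjusted p = 0.258 with an estimated correlation, median 0.478, 0 at the bounds, positive under the same scalings). Anxa2, a membrane-binding protein, was at 4.80 (SE 0.51, adjusted p = 0.00101, 1 control array above background).

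Against 10000 random lists matched on mean level, the diet medians of fatty acid oxidation (100), lipid storage and oxidative phosphorylation (99.8 each) and the matrix and acute phase lists (99.5 each) stood at those percentiles. The macrophage list stood at 96.4, the metal list at 96.1, the hepatocyte list at 94.7, the 1-carbon list at 82.8 and the male-biased list at 0. Receptor genes that the liver does not use stood at 0 for the diet too, and keratins at 0.01. Random genes were drawn independently, so percentiles are too extreme for lists whose members vary together. With an estimated correlation, camera passed 0 lists in either comparison. With DDC the acute phase, fatty acid oxidation, oxidative phosphorylation and endothelial lists lay below every random list (percentile 0), as did the cytosolic ribosomal protein genes. Lipid storage and erythrocyte lists were at 0.04, de novo lipogenesis at 0.02, the metal list at 1.6 and the hepatocyte list at 2.23, while the inflammatory and cholangiocyte lists were at 100 and interferon genes at 99.9. The diet fold change varied with level: with genes put in 10 bins by mean level, the bin medians ran from -0.172 (bin 3 from the dimmest) to 0.273 (bin 7). For genes above background on all 8 arrays, fold changes of the MCD mean against each control alone correlated at 0.77 across genes, with the same sign in 85.0%.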
